A study of Caenorhabditis elegans with 4 samples.

How the data were processed

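The series mapped binding of the transcription factor PHA-4 in late embryos of the nematode Caenorhabditis elegans by chromatin immunoprecipitation followed by sequencing (ChIP-seq). PHA-4 is the worm's FoxA factor, known for specifying the pharynx, the feeding organ. The strain carried a transgene that makes PHA-4 fused to green fluorescent protein (GFP), and an affinity-purified goat antibody against GFP pulled down the crosslinked chromatin, per the labels. Animals were grown at 20 °C and fixed in formaldehyde, per the labels' protocols. The labels describe 2 ChIP libraries and 2 input libraries, 1 of each per replicate. Input is sonicated chromatin DNA that was not immunoprecipitated. Nothing in the labels says whether the replicates came from separate cultures.

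The analysis started from 1 list of peaks for the whole series. Per the file headers, peaks were called with PeakSeq, which compares ChIP with input tags, on the WormBase WS180 genome build. The list is named as combined over the replicates. The aligner, the program versions, the extension of tags and the way in which the libraries were pooled are not given in the sources used here. The deposited list holds, for each peak, a chromosome, a start, an end and the q-value that the authors' caller assigned to it. The q-value is written a second time as an attribute, and the 2 copies were identical in all 9165 peaks. The largest deposited q-value was 0.00997. The list gives no tag counts, fold enrichments or values per library, so the sequencing depth behind each peak is unknown. No test between ChIP and input libraries or between replicates was made.

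Coordinates are 1-based WS180 positions as deposited. The gene table at hand belongs to another build, WBcel235, and neither its coordinates nor a genome sequence was used here. For that reason 3 planned analyses were not run. These were the distance to annotated gene starts, the test of the 14 gene lists fixed in advance, and the search for the FoxA motif. Peaks were therefore described by position. Chromosome lengths of WS180 were not used either. The span from the first peak start to the last peak end stood in for the length of each chromosome, which made 99.98 Mb in all. This stand-in slightly raises every density.

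Peaks were ranked by q-value, with ties ordered by chromosome and start. The tests below and the rule for naming features were fixed before the data were examined, while the stand-in for chromosome length and the bootstrap intervals were chosen afterwards. By that rule the 10 peaks with the best q-values and the 3 densest blocks of about 100 kb were named. Each chromosome's share of peaks was set against its share of the total span with an exact two-sided binomial test, adjusted over the 6 chromosomes by the Benjamini-Hochberg method. As that test treats neighbouring peaks as independent, a permutation of 100 kb blocks across the genome was an alternative, with 100000 resamples. The centre of each autosome, the middle 33.3% of its span, was compared with the rest, called the arms, by shuffling 100 kb blocks within chromosomes (100000 resamples, two-sided). Distances between the midpoints of neighbouring peaks were compared with 1000 uniform placements of the same number of peaks per chromosome. The relation of q-value and width was given as Spearman's rho across peaks, with a permutation p of 100000 resamples. The smallest p that these tests could give was 1e-05 for permutations and 0.001 for placements. Intervals of densities, shares and ratios are 95% bootstrap intervals over 100 kb blocks (10000 resamples, and 1000 for medians). They cover variation along the chromosomes only, not variation between embryos or libraries.

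Alternative settings fixed in advance were the better-scoring 4582 peaks (0.5 of the list), the best-scoring 10%, the list without the widest 5% (peaks over 853 bp), peaks merged where at most 200 bases separated them, a q-value of at most 0.001, blocks of 500 kb and a centre defined as the middle 50% of the span. The limit on the q-value was applied only to the number and the median width of peaks. Other alternatives were chosen after seeing the data. These were merging over up to 1000 bases, placement of each peak within its own 100 kb block, placement with the peak widths and a gap of at least 200 bases kept, rotation of block counts around each chromosome, and leaving out each autosome. The statistics were tested on 20 simulated lists with even placement and 20 with planted changes, each with 9165 peaks. All 20 lists with planted changes gave a call for chromosome V, for autosome centres and for clustering. The planted changes gave a mean ratio of 0.743 for V and a mean of 40.1% of autosomal peaks in the centres. Among the evenly placed lists, chromosome V was called in 2 of 20, and centres and clustering in 0 of 20. A clustering call here meant a share under 5 kb above the highest of a smaller number of placements. Peaks in the even lists were placed independently, so the rate of false calls among clustered peaks was not measured. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used.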

Results

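PHA-4::GFP binding in late embryos was represented by 9165 peaks, in a list combined over 2 replicates, each with a ChIP and an input library. The peaks covered 3407 kb, or 3.41% of the 99.98 Mb that they spanned on the 5 autosomes and the X chromosome. The median peak was 311 bp wide (95% block bootstrap interval 307 to 315), with quartiles at 220 and 438 bp. Of the 9165 peaks, 2951 (32.2%) had a q-value below 1e-10, 213 (2.32%) below 1e-50 and 40 (0.436%) below 1e-100. All q-values are those of the authors' peak caller and served here only to rank, filter and describe peaks within this list. Because the list is combined and holds no tag counts, no value carries a replicate error, and the agreement of the replicates could not be measured.

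The first question was where the best-scoring peaks lay. The peak with the best q-value (1.38e-240) was on chromosome IV from 14032471 to 14034972 (WS180), outside the central part of that chromosome and 7394 bases from its nearest neighbour. The second lay on chromosome II from 11633774 to 11636221 (q = 3.11e-222). Chromosome III held 4 of the 10 best peaks. They were at 8416928 to 8418011 (q = 3.75e-199), 12612193 to 12615770 (q = 4.26e-196), 13060915 to 13063186 (q = 1.77e-185) and 8801277 to 8802666 (q = 4.67e-168). The X chromosome held 3, at 11605261 to 11606597 (q = 1.30e-192), 10765234 to 10768265 (q = 5.43e-190) and 16929262 to 16931964 (q = 7.93e-174). The remaining one was on chromosome I from 7474253 to 7476065 (q = 1.46e-170). Chromosome V, the longest, held 0 of the 10. These 10 peaks were 1084 to 3578 bp wide, and 5 of them lay in the centre of their chromosome, taken as the middle 33.3% of its span. The genes at these positions were not analysed here, since no WS180 annotation was used.

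Peaks with better q-values were wider. The better-scoring 4582 peaks had a median width of 411 bp, the other 4583 peaks 223 bp and the best 10% 638 bp. Across all 9165 peaks, which are not independent replicates, width rose with −log10 of the q-value (Spearman's rho = 0.76, permutation p = 1e-05, the smallest that 100000 resamples can give). Within the best 10% alone, rho was 0.39. PeakSeq tests the tags counted over a whole called region, so width enters the q-value, and without tag counts this relation does not show that stronger binding is wider. At the other end, 1756 peaks (19.2%) were narrower than 200 bp, and 110 of these were narrower than 10 bp. The narrow peaks had a median q-value of 0.00233, and the best of them reached 1.48e-08. A further 158 peaks were exactly 200 bp wide.

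The second question was whether peaks were spread evenly over the chromosomes. They were not. Chromosome III had the highest peak density, with 1598 peaks or 116 per Mb (95% interval 108 to 125), which was 1.27 times the genome mean (1.19 to 1.36). Chromosome V had the lowest peak density, with 1235 peaks or 59.1 per Mb (53.8 to 64.6), which was 0.645 times the mean (0.589 to 0.7004). Both departures passed the exact binomial test (adjusted p = 1.19e-22 for III and 1.09e-74 for V) and the permutation of 100 kb blocks (adjusted p = 3e-05 for each). Chromosome II, with 102 peaks per Mb, also lay above the mean in both tests (1.12 times, adjusted p = 7.21e-06, and 0.0127 by block permutation). Chromosome IV did not differ detectably from the mean (0.978 times, adjusted p = 0.335 by the exact binomial test). Block permutation and the bootstrap intervals treat 100 kb blocks as independent. Where trends are longer, these p-values may be too small and the intervals too narrow. Longer blocks and rotation were not applied to chromosome density.

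On chromosomes I and X the tests differed. Chromosome I had 99.9 peaks per Mb, which was 1.09 times the mean (95% block bootstrap interval 1.01 to 1.17). Its adjusted p was 0.000501 by the exact binomial test and 0.0575 by block permutation. The X chromosome had 96.8 peaks per Mb, which was 1.06 times the mean (0.989 to 1.12), with adjusted p = 0.0152 by the exact binomial test and 0.186 by block permutation. Its ratio was 0.998 among the better-scoring 4582 peaks (0.917 to 1.08) and 1.15 in the best 10% (0.981 to 1.31, adjusted p = 0.0463 by the exact binomial test). The directions for III and V held among the best-scoring peaks. In the best 10% of the list, III stood at 1.42 times the mean (1.23 to 1.63) and V at 0.449 times (0.353 to 0.553). Chromosome I stood at 1.20 times (1.01 to 1.40, adjusted p = 0.0246 by the exact binomial test). Chromosome II stood at 1.17 times (0.965 to 1.37, adjusted p = 0.0463 by the exact binomial test) and IV at 0.857 times (0.711 to 1.02, adjusted p = 0.04996 by the exact binomial test).

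**Figure D1:**
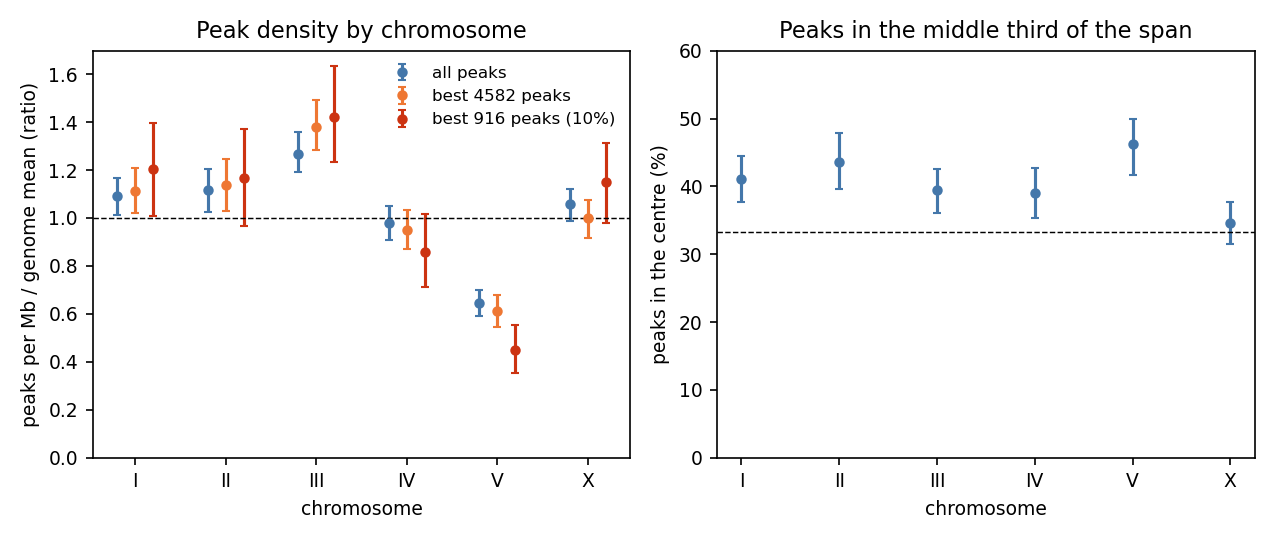
Left, peaks per Mb on each chromosome divided by the genome mean (ratio), for all peaks, the better-scoring 4582 and the best 10%. Right, the percent of a chromosome's peaks in its centre, the middle 33.3% of its span. Points are values, bars are 95% bootstrap intervals over 100 kb blocks, and dashed lines mark an even spread. Chromosome III lies above 1 (1.27) and V below it (0.645) at all levels of q-value, and the X chromosome alone has an interval on the right that includes 33.3%.

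Peaks were denser in the centres of the autosomes than in their outer parts. In C. elegans the autosome centres recombine little, and the outer parts, called arms, are richer in repeats. Densities are per Mb of span. Differences between centres and arms in gene content, or in the share of sequence to which reads map uniquely, were not tested. The centres of the 5 autosomes held 3108 of 7454 peaks, or 41.7% (39.9 to 43.2), where an even spread would give 33.3%. This corresponded to 113 peaks per Mb in the centres and 79.2 per Mb outside them (permutation p = 1e-05 by shuffling 100 kb blocks, the smallest possible). The share was above 33.3% on each autosome. It was 46.2% on V (41.6 to 49.9), 43.7% on II (39.6 to 47.9), 41.0% on I (37.7 to 44.5), 39.5% on III (36.1 to 42.6) and 39.0% on IV (35.4 to 42.7). Each of these passed the block test, with adjusted p between 3e-05 and 0.00463 over the 6 chromosomes. The call for IV ended with 500 kb blocks (adjusted permutation p = 0.0754), and in the best 10% of the list those for III (38.5%, adjusted permutation p = 0.189) and IV (37.96%, adjusted permutation p = 0.35) ended. When block counts were instead rotated around each chromosome, which keeps long-range trends, the pooled autosomes still passed (permutation p = 0.00063) but no single autosome did (adjusted p = 0.26 to 0.588). An autosome allows only as many rotations as it has blocks, from 137 on III to 209 on V. Rotations by a few blocks may also give similar shares, and how far this limits the test was not measured. Before adjustment the permutation p was 0.0664 on I, 0.0867 on III, 0.144 on V, 0.196 on II and 0.588 on IV. On IV, most rotations thus departed from an even share at least as far as the observed counts.

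The X chromosome showed no such concentration that could be detected. Its centre held 592 of 1711 peaks, or 34.6% (31.5 to 37.7, adjusted permutation p = 0.449). The autosomes exceeded the X chromosome by 7.1 percentage points (95% block bootstrap interval 3.44 to 10.5). This interval treats 100 kb blocks as independent and may be too narrow where trends are longer. The contrast was not recomputed under rotation.

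**Figure D2:**
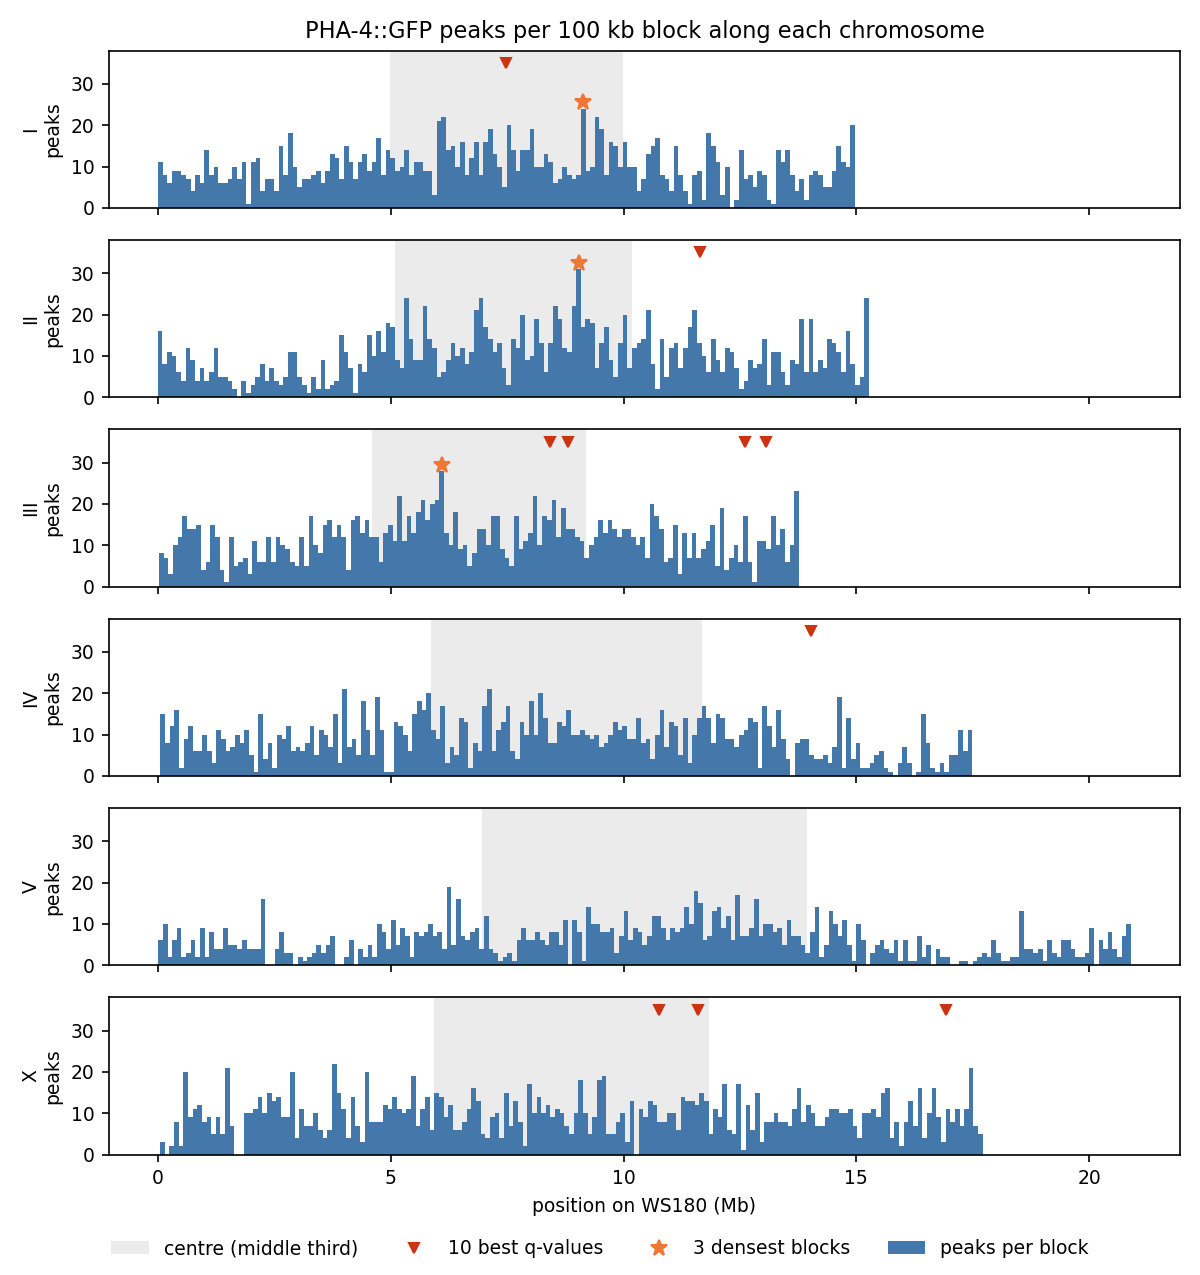
Peaks per block of about 100 kb (vertical axis, count) against position on the WS180 build (horizontal axis, Mb) for chromosomes I to V and X. Grey marks the centre (the middle 33.3% of the span), triangles the 10 best q-values and stars the 3 densest blocks. The tallest block holds 31 peaks on chromosome II, and chromosome V has the most empty blocks (13).

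Peaks varied in number from block to block more than independent placement would give. Over 1000 blocks of about 100 kb the mean was 9.16 peaks with an SD of 5.14, and the variance was 2.89 times the mean. Empty blocks numbered 22, of which 13 were on chromosome V. The densest block was on chromosome II from 8983590 to 9083405, with 31 peaks, a median q-value of 1.55e-07 and a best q-value of 1.38e-132. The next was on chromosome III from 6045672 to 6146006, with 28 peaks. Its peaks scored poorly, with a median q-value of 7.54e-04 and a best of 1.35e-08, and 5 of the 28 were among the better-scoring 4582 peaks. The list has no tag counts with which to tell binding in this block from a difference in DNA copy number. The one after that, on chromosome I from 9084432 to 9184219, had 24 peaks with a median q-value of 1.91e-11, and 18 of them were among the better-scoring 4582. It was tied in number with 3 further blocks, all on chromosome II, and was taken by the order of chromosomes.

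The last comparison asked whether peaks lay closer together than chance. The median distance between neighbouring midpoints was 4684.5 bp, against a mean of 7346 bp in 1000 uniform placements (range 7084 to 7615, two-sided permutation p = 0.001, the smallest possible). Of the 9159 distances, 51.4% were under 5 kb, against 36.4 to 38.9% in the placements. Observed distances were in surplus between 0.5 and 3 kb and again above 30 kb, where distances over 50 kb made up 3.11% against 1.28% in uniform placements. The range from 1 to 2 kb alone held 18.2% of distances where uniform placement gave 8.19%. Distances under 1 kb made up 10.8%, against 8.24 to 10.04% in the placements. The uniform placements treated peaks as points, whereas no 2 peaks in the list were separated by fewer than 200 bases. In placements that kept the peak widths and this gap, 3.66 to 4.97% of distances were under 1 kb, so that the observed 10.8% lay further above them (permutation p = 0.001). The same held among the better-scoring 4582 peaks, with 3.41% observed against 1.01 to 2.25%. In the best 10%, 0% of distances were under 1 kb, within the range of such placements (0 to 0.769%). Against placements of points within each peak's own 100 kb block, the share under 1 kb did not pass (permutation p = 0.22).

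**Figure D3:**
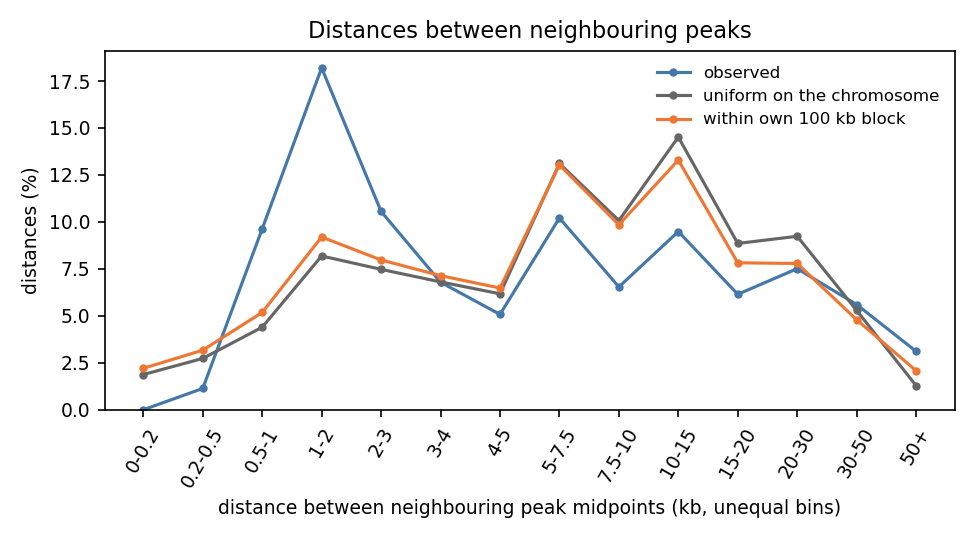
Percent of distances between neighbouring peak midpoints (vertical axis) in unequal bins of distance (horizontal axis, kb). The observed list is compared with 20 of the uniform placements and 20 placements that kept each peak in its own 100 kb block. Observed distances exceed both between 0.5 and 3 kb and above 30 kb, with 18.2% against 8.19% and 9.2% in the bin from 1 to 2 kb.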

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

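Rotation of block counts, placement within blocks or with peak widths, merging over 1000 bases and leaving out an autosome were chosen after the data were seen. Most of the 133 recomputed values kept their direction and their side of the threshold, or stayed within the allowed range. These include every recomputation of the peak density on chromosomes II, III and V by its test (the bootstrap interval of II in the best 10%, 0.965 to 1.37, includes 1), of the pooled autosome centres (40.8 to 42.4% with each autosome left out, and 61.0% with the centre taken as the middle 50% of the span), of the median distance, of the share of distances under 5 kb, and of the relation of q-value and width (rho = 0.39 to 0.74). The number of peaks fell by construction to 4582 in the better-scoring 50% of the list and 916 in the best 10%. The median width rose to 411 and 638 bp in these, and to 347 bp at a q-value of at most 0.001. Block permutation ended the calls for chromosome I (ratio 1.09) and X (1.06), and the call for X also ended without the widest 5% (1.04, adjusted p = 0.12). Chromosome IV was called in the best 10% alone (0.857). For single autosomes the excess in the centre lost its call on IV with 500 kb blocks, on III and IV in the best 10%, and on all 5 under rotation. The ratio of X turned to 0.998 among the better-scoring 4582 peaks, and its share in the centre to 33.2% there and 29.0% in the best 10%, with none of these 3 values passing its test. The share of distances under 1 kb turned below uniform points among the better-scoring 4582 (3.41%) and in the best 10% (0%). Peak width and the gap of 200 bases set this, since with both kept the 3.41% lay above its placements, and the 0% lay within them though below their mean of 0.138% (permutation p = 0.41). At 10.8% the share no longer passed against placements within blocks (permutation p = 0.22), which treated peaks as points and kept neither width nor gap. The cause of the other changes was not tested. Merging at 200 bases joined few peaks (9160 remained) and changed no call. Merging over 1000 bases removes distances under 1 kb by its construction, so that share was not recomputed. No paired analysis was possible because the list is combined and carries no values per library, and for the same reason leaving out a replicate was not run. The alternatives for gene starts, gene lists and the FoxA motif were not run. Depth limits cannot be given, since the list holds no tag counts.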

Other observations

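The comparisons of width, q-value and neighbours between chromosomes were chosen after those data were seen, and merging over 1000 bases and placement within blocks after the file had been examined. Peaks differed in width and q-value between chromosomes. Those on V (median 339 bp) and X (336 bp) were wider than peaks elsewhere, by 32 bp (95% block bootstrap interval 19 to 44) and 30 bp (19 to 41). Peaks on III (287.5 bp) and II (294 bp) were narrower, with differences of -29.5 bp (-39 to -18) and -20 bp (-30 to -11.5). The median −log10 q on III, 6.57, was higher than that of the other chromosomes by 0.797 (0.315 to 1.34). It was lower than elsewhere on X (5.49, a difference of -0.522, -0.884 to -0.0994) and on V (5.55, a difference of -0.444, -0.829 to -0.0263). Widths on I and IV, and −log10 q on I, II and IV, did not differ detectably from elsewhere. None of these intervals was adjusted for the number of comparisons. Of the 10 longest stretches without a peak, 6 were on chromosome V, the longest from 16966000 to 17258253 (292 kb). The last blocks of II and III, at the right ends of these chromosomes, held 24 and 23 peaks, among the 7 highest of the 1000 blocks. High counts were not general at chromosome ends. The first blocks of II and III held 16 and 8 peaks, and the end blocks of the other chromosomes ranged from 3 on X to 20 on I.

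A peak's q-value was not detectably related to its neighbours. Across peaks, Spearman's rho between −log10 q and the number of bases to the nearest peak was -0.01 (adjusted permutation p = 0.349 over 4 relations). Between a peak and the next it was -0.02 for 986 pairs less than 1 kb apart and 0.01 for 3721 pairs from 1 to 5 kb apart (adjusted permutation p = 0.543 for each).

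The low density on chromosome V may have technical or biological roots. Weak calls near the q-value threshold are argued against as the whole cause, because among the better-scoring 4582 peaks the ratio was 0.612 (95% block bootstrap interval 0.546 to 0.679). A few dense blocks elsewhere held too few peaks to make up the shortfall on V. Without the densest 50 blocks the ratio was 0.685 (0.629 to 0.741). No block held more than 31 peaks, so leaving out 50 could not have brought the ratio to 1. That value therefore describes the counts and is not a test. Sparse arms alone do not account for the low density on V. Its centre had 0.659 times the density of the centres of I to IV (0.580 to 0.743), beside 0.532 times for the arms. Differences in gene content or in the share of sequence to which reads map uniquely stay open and were not tested, and the design offers no second stage or factor for a biological test.

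The short distances between peaks could come from single enriched regions split into several calls. After peaks with at most 1000 bases between them were merged, 36.9% of distances were still under 5 kb, above the 29.9 to 32.6% of uniform placements, which argues against splitting over such gaps as the whole cause. Uneven density at 100 kb is argued against in the same way, as 51.4% were under 5 kb against 40.1 to 42.5% when each peak stayed in its own block. Each was tested alone, so splitting and uneven density acting together stay open. Several binding sites per gene, or the spacing of genes, stay open as hypotheses and no biological explanation was tested.

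The dense block on chromosome III held its 28 peaks between 6073763 and 6141790, a stretch of 68.03 kb. The best q-value among them was 1.35e-08, and 60.1% of the whole list scored no better than that. In the stretch 15 of 28 peaks (53.6%) were narrower than 200 bp, against 19.2% of the whole list. The stretch was one of the 3 blocks named by the rule, but its poorly scoring and narrow peaks were noticed in the data. Tests of their scores and widths, run after that, restate what was noticed and are not counted as evidence. Whether the stretch holds many weak binding sites or differs in DNA copy number, through the transgene or otherwise, is not decided by this list, which has no tag counts.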
